A study of Arabidopsis thaliana with 5 samples.

How the data were processed

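Small RNA libraries of 12-day-old Arabidopsis thaliana seedlings were analysed: 1 of Col-0, 2 of mac7-1 and 2 of prl1 prl2. Groups and replicate numbers were taken from the labels. Per the labels' protocols, RNA was extracted with TRIzol, small RNAs were selected on a gel and libraries were made with a NEBNext small RNA kit. Each deposited file lists distinct sequences with counts, which the authors gave as whole read counts without normalization. The submitters' processing notes name CASAVA, with no version, and the TAIR10 genome; the aligner and its settings are not given in the sources used here. The files held sequences of 18 to 42 nt, and 99.9998% of the reads of every library matched the genome exactly, so reads without a match had already been removed from what was analysed. Sequences were matched to the TAIR10.1 reference with its RefSeq annotation, and all coordinates are of that build.

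Between 99.7% and 99.8% of the reads were listed in the forward orientation of the genome, which means that the strand of origin was not kept. A sequence and its reverse complement were therefore merged, sense and antisense reads were not told apart, and the planned analysis of the first base was not possible. The file of prl1 prl2 replicate 1 was damaged: a stretch of its alphabetical list of sequences was missing, and 387313 sequences, with 1750276 reads, were repeated with identical counts. The repeats were dropped. The missing stretch held 21.8% of the Col-0 reads, 21.9% and 21.1% of the mac7-1 reads and 23.8% of the reads of prl1 prl2 replicate 2. Reads outside that stretch on either strand numbered 2759650 in Col-0, 2433742 and 2355443 in mac7-1, and 3752455 and 5926064 in prl1 prl2. The reference gives 428 mature miRNAs with 350 distinct sequences, of which 271 lie outside the missing stretch and 79 inside it. This required a departure from the design: the 271 were fitted over all 5 libraries with the reads outside the stretch as library size, and the 79 over the 4 other libraries with all reads as library size, after which p-values were adjusted together. Levels are given in RPM, the reads of a feature scaled to the same library sizes. Shares of reads, trans-acting siRNA genes, 24-nt windows and gene counts use only reads outside the stretch.

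A read counted for a mature miRNA when its sequence equalled the mature sequence, and identical mature sequences of several genes were 1 item. miRNAs with a mean of at least 5 RPM were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with total reads as library size, no composition factor and all groups in 1 model. The fit had 2 residual degrees of freedom with 5 libraries and 1 with 4, and the spread of Col-0 was taken from the mutants. Benjamini-Hochberg adjusted p-values under 0.05 were called; all tests were two-sided. Standard errors (SE) were derived from the F statistic. The 8 TAS genes were tested on 21-nt reads together with the miRNAs. For 24-nt siRNAs, reads with 1 genome match were counted in 1-kb windows with a mean of at least 10 reads, without MIR genes. 21-nt reads per protein-coding gene, without those on MIR or TAS genes, were tested in the same way, a choice made after seeing the data. Lists of miRNAs (conserved, lineage-restricted, nutrient-responsive, RNA silencing targets, secondary-siRNA triggers, developmental regulators, DCL4-processed and intron-hosted) were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1 on the miRNAs seen in all 5 libraries. DESeq2 1.42.0 served as the other test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for counting and plots.

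The groups, designs, lists, alternatives and the rule for named features were fixed before the data were examined. The rule named, for each mutant against Col-0, the 10 most abundant miRNAs, the 10 largest falls and 5 largest rises past adjusted p 0.05 whose libraries both lay on 1 side of Col-0, and the tested members of the silencing-target, trigger and DCL4 lists. Between the mutants it named the 5 largest differences in each direction without overlap of libraries; it also named all TAS genes and the 3 largest window changes in each direction. The alternatives were TMM factors, DESeq2 size factors, rRNA-matching reads, 18 to 28 nt reads or nuclear reads without structural RNA as library scale; the DESeq2 Wald test; no filter or 20 RPM; mature reads with ends within 2 nt and 3 nt; reads of 20 to 24 nt per MIR gene; only the groups compared; the replicate number as a block; each mutant library left out; windows of 500 bp, at least 30 reads, or reads with several matches split; 20 to 22 nt reads for TAS genes; and an estimated correlation for lists. After seeing the data, the miRNAs outside the missing stretch alone, reads of lengths other than 24 nt as library size, nuclear reads as the scale for windows, and all reads of the 4 intact libraries for TAS genes were added.

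The tests were checked on simulated counts drawn from the real means. For mac7-1 against Col-0, the miRNA test on 83 items found 21.5% of 2-fold and 63.2% of 4-fold changes, with 0.5 unchanged items called per run. For mac7-1 against prl1 prl2 it found 32.5% and 89.8%, with 0.8 called. With the changes placed in prl1 prl2 instead, prl1 prl2 against Col-0 gave 13.5% and 69.5%, with 0.35 called. The window test for mac7-1 against Col-0 on 14548 windows found 10.2% and 63.4%, with 3.2 called. The gene test for prl1 prl2 against Col-0 on 213 genes found 36% and 91.3%, with 1.1 called. Shares of the single Col-0 library carry a Wilson 95% interval. Where a group had 0 reads, folds were set against 3 counts over the group's reads. Such intervals and floors cover counting error only, since amplified reads are not independent molecules. Replicates were compared before use: the chi-square per degree of freedom over 83 miRNAs was 46.8 for mac7-1 and 215.8 for prl1 prl2, so neither pair was a single library deposited again.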

Results

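Small RNAs were sequenced from 12-day-old Arabidopsis seedlings of 3 genotypes: wild-type Col-0 (1 library), mac7-1 (2 libraries) and the double mutant prl1 prl2 (2 libraries). MAC7, PRL1 and PRL2 are components of the MOS4-associated complex, which associates with the spliceosome, and the comparisons ask how their loss alters miRNAs and other small RNAs. The Col-0 library held 3758617 reads, the mac7-1 libraries 3369886 and 3216097, and the prl1 prl2 libraries 4102617 and 8449996. In prl1 prl2 replicate 1 a stretch of sequences was missing, so 79 of 350 mature miRNA sequences were compared without that library and the others in all 5. Values named for 4 libraries below rest on prl1 prl2 replicate 2 alone in that genotype. In those fits only the 2 mac7-1 libraries gave a spread within a group, so prl1 prl2 had none of its own. The labels do not say that replicates were separate pools of plants, so p-values measure the spread between these libraries, which may be technical, and Col-0 has no spread of its own.

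Few reads matched the mutated genes. MAC7 (AT2G38770, chromosome 2, 16202942 to 16210428) had 7 reads in Col-0, 8 and 4 in mac7-1, and 19 and 16 in prl1 prl2. PRL1 (AT4G15900, chromosome 4, 9023666 to 9027808) had 1 read in Col-0, 4 and 2 in mac7-1, and 6 and 5 in prl1 prl2. PRL2 (AT3G16650, chromosome 3, 5671018 to 5675438) had 1 read in Col-0, 2 and 0 in mac7-1, and 9 and 14 in prl1 prl2. Small RNA reads do not measure messenger RNA, so these values check no genotype.

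The mutants differed from Col-0 in opposite ways in their share of miRNAs. Mature miRNAs took 11.4% of the reads in Col-0 (Wilson 95% interval 11.35% to 11.43%), 15.3% ± 0.525 (SD, n = 2) in mac7-1 and 8.79% ± 1.63 (SD, n = 2) in prl1 prl2. Reads of 21 nt, the usual length of miRNAs and trans-acting siRNAs, were 19.3% of the 18 to 30 nt reads in Col-0, 22.2% ± 0.32 (n = 2) in mac7-1 and 13.8% ± 1.46 (n = 2) in prl1 prl2. Reads of 24 nt, the usual length of siRNAs that direct DNA methylation, were 40.8% in Col-0, 35.2% ± 1.63 in mac7-1 and 42.04% ± 0.44 in prl1 prl2. In each case the mutant mean differed from Col-0 by more than the SD between the mutant's libraries, but with 1 Col-0 library no test was made. Leaving out prl1 prl2 replicate 1 or 2 changed the difference in miRNA share from -2.60 points to -1.44 or -3.76.

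**Figure D1:**
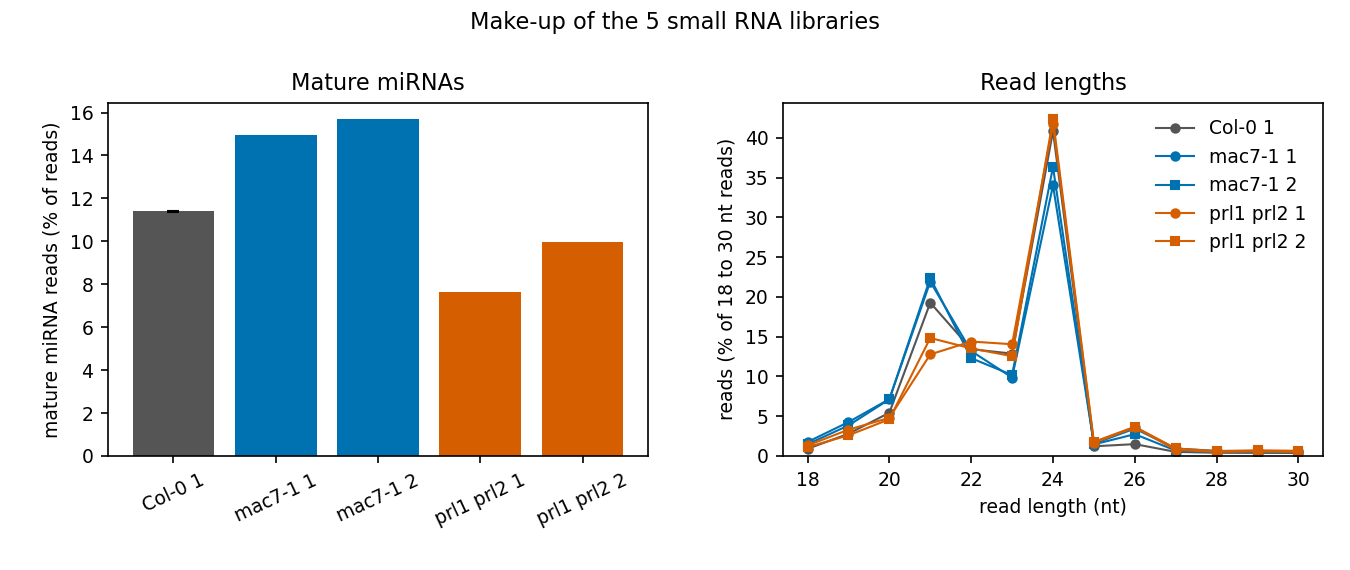
Share of mature miRNA reads (percent of reads, left; the error bar on Col-0 is its Wilson interval) and read lengths (percent of 18 to 30 nt reads, right) in each of the 5 libraries. The miRNA share was 11.4% in Col-0, above it in both mac7-1 libraries and below it in both prl1 prl2 libraries.

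Reads of other RNA classes moved too. Chloroplast reads were 11.4% in Col-0, 14.9% ± 1.71 (SD, n = 2) in mac7-1 and 17.4% ± 0.55 (n = 2) in prl1 prl2, and mitochondrial reads 0.764%, 0.931% ± 0.107 and 1.25% ± 0.202. Reads of small nuclear and nucleolar RNAs were 0.185% in Col-0, 0.343% ± 0.072 in mac7-1 and 0.423% ± 0.143 in prl1 prl2. Fragments of ribosomal RNA were 0.0715%, 0.0977% ± 0.0168 and 0.0926% ± 0.00765, and those of transfer RNA 0.0071%, 0.0150% ± 0.00331 and 0.0159% ± 0.00421. Reads in protein-coding exons were 8.81%, 8.32% ± 0.341 and 8.69% ± 0.0163, and reads in introns 3.48%, 2.89% ± 0.175 and 3.49% ± 0.152. Over 44 abundant miRNAs, the median share of reads that began at the annotated 5′ end was 95.5% in Col-0, 95.9% ± 0.0304 in mac7-1 and 95.2% ± 0.408 in prl1 prl2. The median share that ended at the annotated 3′ end was 76.9% in Col-0, 70.5% ± 1.27 in mac7-1 and 67.6% ± 2.7 in prl1 prl2. These medians were taken within each library, and single miRNAs went both ways. miR159a was at 76.7% in Col-0, 81.5% and 76.5% in mac7-1, and 84.5% and 84.4% in prl1 prl2. miR164a/b-5p was at 77.0% in Col-0, 72.5% and 71.8% in mac7-1, and 59.9% and 68.1% in prl1 prl2.

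In mac7-1, the miRNAs with the largest rise were those of miR395, which targets ATP sulfurylases and a sulfate transporter. miR395a/d/e rose 10.9-fold, from 265 RPM in Col-0 to 2897 ± 202 (SD, n = 2; log2 fold change 3.45 ± 0.73 SE, adjusted p = 0.000545). miR395b/c/f, measured in 4 libraries, rose 9.96-fold from 269 to 2679 ± 290 RPM (adjusted p = 0.00134). Rises were also seen for miR5650, encoded within an intron (1.45 to 11.4 ± 3.57 RPM, adjusted p = 0.0168), for miR393a-3p (4.71 to 21.3 ± 2.46, adjusted p = 0.0151) and for miR775 (14.1 to 60.6 ± 6.72, adjusted p = 0.0141). miR3932b-5p fell from 397.2 to 89.2 ± 6.49 RPM (log2 fold change -2.15 ± 0.63 SE, adjusted p = 0.0151), and miR5996, in 4 libraries, from 26.3 to 6.12 ± 2.78 RPM (adjusted p = 0.0313).

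The 10 most abundant miRNAs did not pass the test in mac7-1, although 8 of them were higher in both of its libraries than in Col-0. The exceptions were miR159b-3p, which targets MYB transcription factors (29957 RPM in Col-0 and 31460 ± 2220 in mac7-1, adjusted p = 0.894), and miR166a/b/c/d/e/f/g-3p (6905 and 6783 ± 278). miR156a/b/c/d/e/f-5p, which targets SPL transcription factors, was at 6884 and 12509 ± 813 (adjusted p = 0.17), and miR5026 at 3294 and 8151 ± 1880 (adjusted p = 0.0609). The related miR157a/b/c-5p was at 4020 and 6790 ± 281 RPM, miR396b-5p at 6756 and 12733 ± 3010, and miR161.1 at 2516 and 3568 ± 345. miR159a was at 21826 and 27321 ± 1180 RPM, and miR158a-3p at 20379 and 26882 ± 56.5. With only the groups compared miR162a/b-3p, miR396b-5p, miR156a/b/c/d/e/f-5p, miR5026 and miR157a/b/c-5p were called higher (adjusted p = 0.0176 to 0.0351), as they were without prl1 prl2 replicate 1 (adjusted p = 0.0267 to 0.0468) or 2 (adjusted p = 0.0184 to 0.0357). Without replicate 2 miR158a-3p was called too (adjusted p = 0.0377). miR162a/b-3p was also called by the DESeq2 Wald test (adjusted p = 0.0247), without a filter (adjusted p = 0.0134), with 18 to 28 nt reads (adjusted p = 0.0270) or nuclear reads as the scale (adjusted p = 0.0128) and with reads of other ends (adjusted p = 3.67e-05). miR5026 was called with nuclear reads (adjusted p = 0.0385).

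By list, the conserved miRNAs of mac7-1 had 6 of 53 measured members higher and 0 lower, with 8 higher when adjusted over the list alone. Of 48 lineage-restricted miRNAs 3 rose and 2 fell, also when adjusted over the list alone. The 41 of them seen in all 5 libraries were ranked below the other miRNAs by camera. Over the 48 the median (0.47) and mean (0.40) log2 fold changes were positive. Of 9 nutrient-responsive miRNAs 2 rose, and 4 when adjusted over the list alone. Among 36 developmental regulators 3 rose, and 0 when adjusted over the list alone. Of 8 intron-hosted miRNAs 2 rose, miR5650 and miR5024-3p, on either adjustment. The lists of secondary-siRNA triggers and of silencing targets hold both strands of their families. Of 7 members of the trigger list 2 rose on either adjustment, both of them 3p strands: miR393a-3p and miR390a-3p (22.1 to 49.3 ± 3.77 RPM, adjusted p = 0.046). The strands that trigger TAS siRNAs did not pass: miR390a/b-5p was at 26.5 and 41.5 ± 1.11 RPM (adjusted p = 0.418) and miR173-5p at 22.8 and 27.3 ± 2.62 (adjusted p = 0.772). miR393b-3p was called higher with only the groups compared (adjusted p = 0.0265) and without prl1 prl2 replicate 1 or 2 (adjusted p = 0.0337 and 0.0252), and miR403-3p without replicate 2 (adjusted p = 0.0400). The 7 members of the silencing-target list had 0 calls on either adjustment; miR162a/b-3p, which targets DCL1, was at 8094 RPM in Col-0 and 13348 ± 2320 in mac7-1 (adjusted p = 0.0696). Of the DCL4-processed list only miR822-5p was measured, at 18.4 and 11.2 ± 1.78 RPM (adjusted p = 0.232, and 0.0333 with DESeq2 size factors). By camera, which compares a list with the other miRNAs, 0 of 7 lists passed and 1 had an unadjusted p under 0.05; by fry, which asks whether a list moves 1 way on balance without comparing it with others, the intron-hosted list did (adjusted p = 0.0247).

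The edgeR test called 11 of 103 miRNAs in mac7-1, 9 higher and 2 lower. The 3 called outside the naming rule, miR164c-5p, miR396b-3p and miR5024-3p, were higher and are named after their values were seen. The median log2 fold change of all tested miRNAs was 0.61. It was -0.06 with TMM factors (3 higher, 4 lower), -0.01 with DESeq2 size factors (4 higher, 6 lower) and 0.20 with rRNA reads as the scale (2 higher, 2 lower); TMM and DESeq2 factors were computed from the miRNAs, which centres their changes. miR390a-3p, miR393a-3p, miR5650 and miR5996 were not called with TMM factors (adjusted p = 0.0526 to 0.475) or by the DESeq2 Wald test (adjusted p = 0.056 to 0.188). With rRNA reads as the scale miR390a-3p, miR393a-3p, miR5650 and miR775 were not called (adjusted p = 0.198 to 0.557), with DESeq2 size factors miR390a-3p and miR5650 (adjusted p = 0.0663 to 0.323), and with reads of other ends miR775 (adjusted p = 0.0995). Reads of other lengths than 24 nt as library size, a scale chosen after seeing the data, ended the calls of miR390a-3p (adjusted p = 0.127) and miR5996 (adjusted p = 0.0851), and a filter at 20 RPM that of miR390a-3p (adjusted p = 0.0515). Without mac7-1 replicate 1 edgeR called 0 miRNAs (2 at an unadjusted p under 0.05, and 1 by DESeq2), and without mac7-1 replicate 2 it called 0 (8 at an unadjusted p under 0.05, and 1 by DESeq2); miR395a/d/e then had adjusted p = 0.087 and 0.0718, with log2 fold changes of 3.52 and 3.38, and the other named calls still testable adjusted p up to 0.688 and 0.497. Without prl1 prl2 replicate 1 it called 25 and without prl1 prl2 replicate 2 it called 30.

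**Figure D2:**
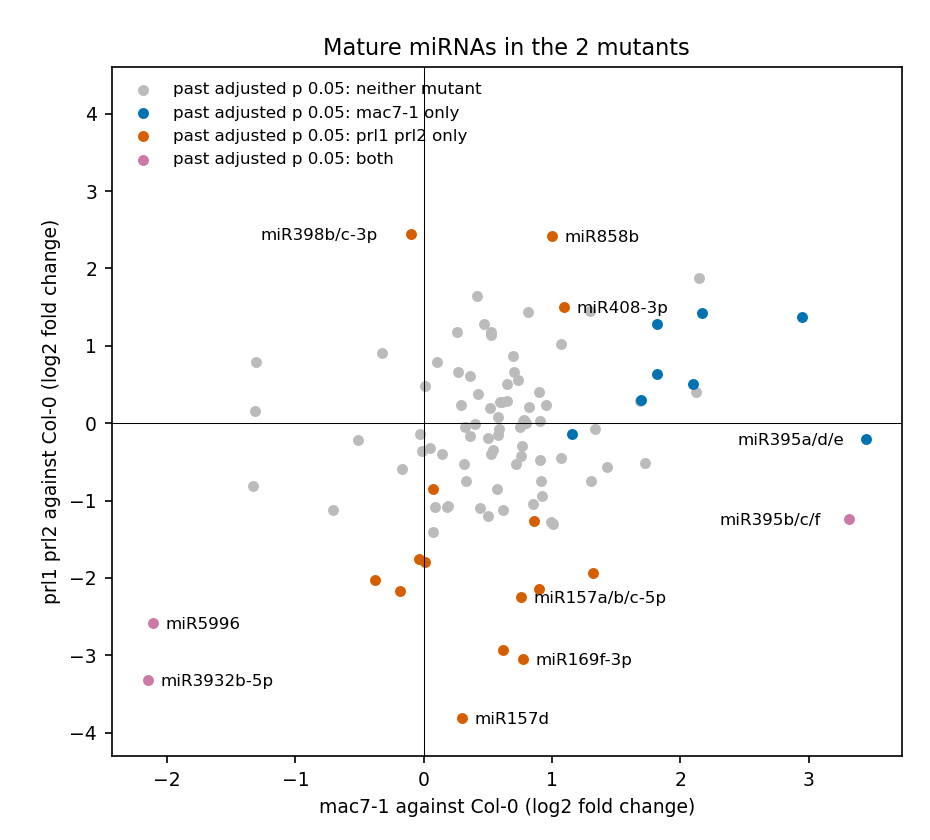
Log2 fold change against Col-0 of 103 mature miRNAs in mac7-1 (horizontal axis) and prl1 prl2 (vertical axis), coloured by the mutants in which adjusted p was under 0.05. Most points lie to the right of 0 on the horizontal axis, where the median was 0.61, a shift that TMM and DESeq2 factors removed; the miR395 family stands apart at 3.45 and 3.32.

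In prl1 prl2, several miRNAs fell, some that control development among them. miR157d fell 13.99-fold, from 151 RPM in Col-0 to 10.7 ± 3.77 (SD, n = 2; log2 fold change -3.81 ± 0.64 SE, adjusted p = 1.33e-06), though its reads match 4 places in the genome. miR157a/b/c-5p, which targets SPL transcription factors, fell 4.73-fold from 4020 to 849 ± 357 RPM (adjusted p = 8.04e-05), and the related miR156a/b/c/d/e/f-5p 2.41-fold from 6884 to 2861 ± 144 (adjusted p = 0.0143). miR169f-3p fell from 35.5 to 4.23 ± 0.703 RPM (adjusted p = 1.83e-06) and miR3932b-5p from 397.2 to 39.7 ± 2.98 (adjusted p = 1.71e-05; its reads match 2 places). The largest rise among miRNAs seen in all libraries was that of miR398b/c-3p, which targets copper/zinc superoxide dismutases, 5.44-fold from 844 to 4588 ± 2210 RPM (log2 fold change 2.44 ± 0.62 SE, adjusted p = 0.00189).

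Smaller pools changed as well. miR8183 fell from 10.15 to 1.40 ± 1.03 RPM (adjusted p = 0.000493), miR159c from 93.1 to 22.7 ± 5.66 and miR167c-3p from 13.045 to 2.95 ± 0.352 (both adjusted p = 0.00267), and miR158a-5p from 87.7 to 22.8 ± 4.31 (adjusted p = 0.0162). The abundant miR159b-3p fell 1.8-fold, from 29957 to 16645 ± 3030 RPM (adjusted p = 0.0189). In 4 libraries, miR5996 fell from 26.3 to 4.38 RPM (adjusted p = 0.0148) and miR168b-3p from 115 to 25.6 (adjusted p = 0.0414). Also in 4 libraries, miR408-3p, which targets copper proteins, was called higher (414 to 1175 RPM), as was miR858b, whose reads match 2 places (4.26 to 22.8). Reads near miR408-5p, the other strand, could be seen in both prl1 prl2 libraries. They numbered 664 of 2759650 in Col-0, 981 of 3752455 in prl1 prl2 replicate 1 and 4225 of 5926064 in replicate 2. On that strand replicate 1 was thus close to Col-0 and only replicate 2 clearly above it. Other abundant miRNAs did not pass: miR159a was at 21826 RPM in Col-0 and 21059 ± 4550 in prl1 prl2, miR158a-3p at 20379 and 20320 ± 1540, miR162a/b-3p at 8094 and 5633 (4 libraries), miR396b-5p at 6756 and 4032 ± 2260, miR166a/b/c/d/e/f/g-3p at 6905 and 6250 ± 2460, miR5026 at 3294 and 1968 ± 456, and miR161.1 at 2516 and 1094 ± 767. Without prl1 prl2 replicate 2 the log2 fold changes were -1.47 for miR396b-5p, -0.61 for miR166a/b/c/d/e/f/g-3p, -1.001 for miR5026 and -2.19 for miR161.1. These set 1 library against 1, with the spread of mac7-1. miR396b-5p, miR5026 and miR161.1 were below Col-0 in both prl1 prl2 libraries. For miR166a/b/c/d/e/f/g-3p the libraries disagreed, with 4509 RPM in replicate 1 and 7990 in replicate 2, against 6905 in Col-0. With reads of other ends miR162a/b-3p was called lower (-0.46, adjusted p = 0.0202).

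Of 36 developmental regulators 6 fell and 0 rose in prl1 prl2, on either adjustment, beside 15 lower and 3 higher of all 103 tested miRNAs. Their median log2 fold change was -0.46. On the 29 seen in all 5 libraries camera gave an adjusted p of 0.0671. By camera the 6 nutrient-responsive miRNAs seen in all 5 libraries ranked above the other miRNAs (adjusted p = 0.0325). With an estimated correlation its adjusted p was 0.677. Of all 9 measured members 2 were up and 1 down on either adjustment. Those up were miR398b/c-3p and miR408-3p, which repress copper proteins, while miR395b/c/f was down (269 to 114 RPM). miR408-3p and miR395b/c/f rest on prl1 prl2 replicate 2 alone and were not in the camera test. The related miR395a/d/e, seen in both prl1 prl2 libraries, was at 265 RPM in Col-0 and 230 ± 3.38 (adjusted p = 0.869). Of 53 conserved miRNAs 2 rose and 9 fell, of 48 lineage-restricted ones 1 rose and 6 fell, and of 8 members of the intron-hosted list 1 fell, all on either adjustment. The last was miR156a/b/c/d/e/f-5p, of whose genes only MIR156d lies in an intron, so its fall need not be that of an intron-hosted miRNA. Of the 7 members of the silencing-target list 1 fell, miR168b-3p, and 0 when adjusted over the list alone; the other strand, miR168a/b-5p, which targets AGO1, was not called (173.2 RPM in Col-0 and 199 ± 140, adjusted p = 0.885), with miR403-3p, which targets AGO2, at 1660 and 1608 ± 389. The 7 members of the trigger list had 0 calls on either adjustment; miR173-5p, which triggers TAS1 and TAS2 siRNAs, was at 22.8 RPM in Col-0 and 51.8 ± 16.7 (adjusted p = 0.113), and miR390a/b-5p, which triggers TAS3 siRNAs, at 26.5 and 37.5 ± 23.6 (adjusted p = 0.595). Some members were called under alternatives: miR173-5p, miR393a-3p and miR472-5p higher with TMM factors (adjusted p = 0.0178, 0.0177 and 0.0255) and DESeq2 size factors (adjusted p = 0.00978, 0.00814 and 0.0366). With prl1 prl2 replicate 2 alone, the log2 fold changes of miR173-5p, miR393a-3p and miR390a/b-5p were 1.41, 1.69 and 0.97. With replicate 1 alone that of miR393b-3p was -1.15. The libraries disagreed for miR390a/b-5p, at 20.8 RPM in replicate 1 and 54.2 in replicate 2. The DCL4-processed miR822-5p was at 18.4 and 8.40 RPM (adjusted p = 0.0905, and 0.0499 with rRNA reads as the scale). By camera 1 of 7 lists passed; by fry 0 did, with 0 at an unadjusted p under 0.05. Of the miRNAs seen in all 5 libraries, camera ranked 41 lineage-restricted and 4 silencing-target members above the others. Over all 48 and 7 measured members, which camera did not test as a set, medians were 0.01 and -0.05. The means were -0.15 and -0.37.

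The edgeR test called 18 of 103 miRNAs in prl1 prl2, 3 higher and 15 lower, with a median log2 fold change of -0.14. With factors computed from the miRNAs themselves there were 10 higher and 8 lower by TMM (median 0.24), and 14 higher and 16 lower by DESeq2 size factors (median 0.08). With nuclear reads as the scale there were 6 higher and 14 lower (median -0.02), and with rRNA reads 1 higher and 14 lower (median -0.49). miR398b/c-3p, miR159b-3p and miR408-3p were not called with rRNA reads as the scale (adjusted p = 0.0657, 0.0858 and 0.321), miR858b, miR5996 and miR159b-3p not by the DESeq2 Wald test (adjusted p = 0.16, 0.123 and 0.253), and miR5996, miR168b-3p, miR167c-3p, miR158a-5p, miR159b-3p and miR156a/b/c/d/e/f-5p not with TMM factors (adjusted p = 0.0511 to 0.125). Leaving out mac7-1 replicate 1 or 2 left 6 calls each and ended those of miR167c-3p, miR159c, miR158a-5p, miR159b-3p and miR156a/b/c/d/e/f-5p (adjusted p = 0.0983 to 0.475 and 0.137 to 0.47). With only the groups compared the test called 6, without miR159c, miR158a-5p, miR159b-3p and miR156a/b/c/d/e/f-5p (adjusted p = 0.243 to 0.456). Reads of other lengths than 24 nt as library size, a scale chosen after seeing the data, ended the calls of miR858b, miR5996 and miR168b-3p (adjusted p = 0.0584 to 0.109). miR159b-3p was also not called with nuclear reads as the scale (adjusted p = 0.0718), without a filter (adjusted p = 0.0975) or with reads of other ends (adjusted p = 0.0955). Without prl1 prl2 replicate 1 the test called 28; the call of miR167c-3p ended without prl1 prl2 replicate 1 (adjusted p = 0.0539) or 2 (adjusted p = 0.0888).

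**Figure D3:**
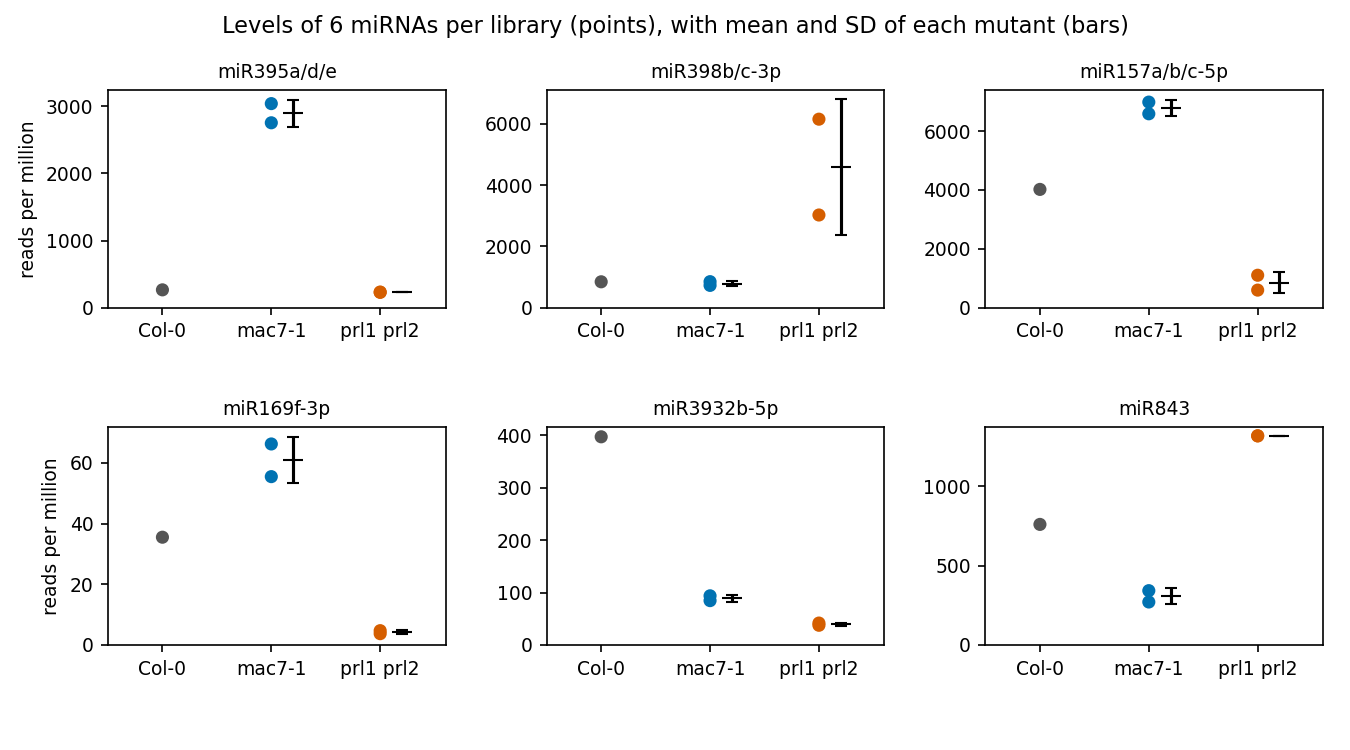
Levels in RPM of 6 miRNAs in each library (points), with the mean and SD of each mutant (bars). miR395a/d/e was higher in mac7-1 than in the other genotypes, miR398b/c-3p higher in prl1 prl2, and miR157a/b/c-5p and miR169f-3p lower in prl1 prl2 at these total-read scales.

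Set against each other directly, the mutants differed in 48 of 103 miRNAs by edgeR, 44 higher in mac7-1 and 4 higher in prl1 prl2. Higher in mac7-1 were miR395b/c/f (23.5-fold, 4 libraries, adjusted p = 4.47e-05), miR157d (17.2-fold, adjusted p = 3.13e-09), miR169f-3p (14.1-fold, 60.9 ± 7.61 against 4.23 ± 0.703 RPM, adjusted p = 2.45e-11), miR395a/d/e (12.6-fold, adjusted p = 1.12e-08) and miR8183 (11.8-fold, adjusted p = 9.96e-08). Higher in prl1 prl2 were miR398b/c-3p (5.83-fold, 787 ± 86.3 against 4588 ± 2210 RPM, adjusted p = 2.39e-06), miR843 (4.3-fold, 307 ± 50.5 against 1317 ± 0.399 RPM, adjusted p = 0.00105), miR391-5p (2.76-fold, adjusted p = 0.0203) and miR858b (2.67-fold, adjusted p = 0.0179). Of the developmental regulators 23 of 36 were higher in mac7-1 and 0 lower (24 when adjusted over the list alone). On the 29 seen in all 5 libraries camera gave an adjusted p of 0.06. Of the conserved miRNAs 29 of 53 were higher and 1 lower (30 and 1). The other lists had 14 of 48 lineage-restricted members higher and 3 lower, 3 of 8 intron-hosted, miR156a/b/c/d/e/f-5p among them (fry adjusted p = 0.0157), 3 of 7 silencing-target, 2 of 7 trigger and 2 of 9 nutrient-responsive members higher, the last with 1 lower, all on either adjustment. By camera 0 of 7 lists passed, with 3 at an unadjusted p under 0.05. It tested only members seen in all 5 libraries. Of these it ranked 41 lineage-restricted, 4 silencing-target, 6 trigger and 6 nutrient-responsive members below the other miRNAs. Over all measured members of these lists, in the same order, medians (0.53, 0.80, 0.34 and 0.05) and means (0.55, 0.95, 0.42 and 0.55) were positive.

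Scales not computed from the miRNAs kept most calls higher in mac7-1: 27 higher and 3 lower with rRNA reads, 44 and 4 with 18 to 28 nt reads, 43 and 4 with nuclear reads, and 37 and 7 with reads of other lengths than 24 nt, a scale chosen after seeing the data. With TMM factors, which centre the changes of the miRNAs, 12 were higher in mac7-1 and 21 lower (median -0.22, against 0.75). With DESeq2 size factors, which do the same, 19 were higher and 23 lower (median -0.04). The call of miR391-5p ended with rRNA reads as the scale (adjusted p = 0.0511), by the DESeq2 Wald test (adjusted p = 0.118), and without mac7-1 replicate 1 (log2 fold change -0.92, adjusted p = 0.525), mac7-1 replicate 2 (-2.33, adjusted p = 0.0837) or prl1 prl2 replicate 2 (-0.93, adjusted p = 0.271), against -1.47 with all libraries; that of miR858b ended by the Wald test (adjusted p = 0.24). Without mac7-1 replicate 1 the test called 13 miRNAs and without mac7-1 replicate 2 it called 14, and miR843 then had adjusted p = 0.0673 and 0.126.

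The mutants were compared with the same Col-0 library, which ties their fold changes together. Across the 83 miRNAs seen in all 5 libraries, which are not independent replicates, the correlation of the fold changes was 0.249, against 0.672 in 100 simulations of unchanged mutants. The covariance was 0.255 against 0.25 simulated, a difference of 0.00505. Of these miRNAs 1, miR3932b-5p, was called lower in both mutants, against 0.145 for independent lists and 0 in the simulations. By edgeR 0 were higher in both, against 0.0843 for independent lists and 0.01 in the simulations.

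Trans-acting siRNAs, the 21-nt siRNAs cut from TAS transcripts after a miRNA triggers them, differed mainly in prl1 prl2. Reads of TAS1C fell from 31724 RPM in Col-0 to 11552 ± 1330 (SD, n = 2; log2 fold change -1.46 ± 0.24 SE, adjusted p = 0.00013), those of TAS1A from 11065 to 3790 ± 331 (-1.55 ± 0.31 SE, adjusted p = 0.00122) and those of TAS1B from 2558 to 957 ± 309 (-1.42 ± 0.50 SE, adjusted p = 0.0498). These are reads outside the missing stretch, on which the size of the fall of TAS1A depended: in prl1 prl2 replicate 2 it was 3.11-fold outside the stretch, 1.09-fold inside it and 1.96-fold over all reads (11270 to 5747 RPM). Over all reads of that library TAS1B fell 3.43-fold and TAS1C 3.06-fold, the latter 2.99-fold outside the stretch and 1.61-fold inside it. TAS2 depended on the stretch in the other direction: it was 1.49-fold lower outside, 2.88-fold lower inside and 1.72-fold lower over all reads of that library. TAS4, whose siRNAs target MYB genes of anthocyanin synthesis, rose 7.85-fold in prl1 prl2, from 186 to 1463 ± 439 RPM (adjusted p = 0.00256). In mac7-1 TAS4 was at 721 ± 8.41 RPM and TAS1A, TAS1B and TAS1C at 11855 ± 114, 1446 ± 1.55 and 30250 ± 959. TAS2 was at 5189 RPM in Col-0, 4911 ± 681 in mac7-1 and 4251 ± 1080 in prl1 prl2, and TAS3A, whose siRNAs target ARF genes, at 536, 524 ± 3.53 and 228 ± 15.9. TAS3B was at 16.7, 22.5 ± 1.84 and 18.8 ± 0.173 RPM, and TAS3C at 16.3, 16.3 ± 2.74 and 9.59 ± 3.78.

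Of the 8 TAS genes edgeR called 4 in prl1 prl2, also when adjusted over the list alone, and 0 in mac7-1, where only TAS4 had an unadjusted p under 0.05 (0.00481; adjusted p = 0.0548, and 0.0385 when adjusted over the list alone). Between the mutants TAS1A (log2 fold change 1.65, adjusted p = 5.93e-05) and TAS1C (1.39, adjusted p = 1.92e-05) were higher in mac7-1, on either adjustment; with TMM factors neither passed (adjusted p = 0.0866 and 0.178) and TAS4 was lower in mac7-1 instead (-1.98, adjusted p = 0.0051). TMM factors also ended the call of TAS1B in prl1 prl2 (adjusted p = 0.164). Without mac7-1 replicate 1 or 2 the calls of TAS1A (adjusted p = 0.067 and 0.066) and TAS1B (adjusted p = 0.229 and 0.252) in prl1 prl2 ended, which left 2. Without prl1 prl2 replicate 1 or 2, mac7-1 had 2 calls: TAS4 higher (adjusted p = 0.0154 and 0.015) and TAS1B lower (adjusted p = 0.0427 and 0.0416). TAS3A in prl1 prl2 then had log2 fold changes of -1.31 and -1.17. In these fits prl1 prl2 had 1 library, and only the mac7-1 pair gave a spread. With all reads of the intact libraries, a choice made after seeing the data, the same held, with prl1 prl2 replicate 2 alone. In mac7-1 TAS4 was then at 1.97 and TAS1B at -0.73 against Col-0. In prl1 prl2 TAS1A was at -0.97, TAS1B at -1.78, TAS1C at -1.62, TAS3A at -1.39 and TAS4 at 3.22. Between the mutants TAS4 was lower in mac7-1 (-1.24) and the others higher, by 0.15 (TAS3B) to 1.54 (TAS1C). TAS2 differed by 0.73, which replicate 1 does not share. Outside the stretch TAS2 was at 5013 RPM in replicate 1 and 3488 in replicate 2, against 5189 in Col-0.

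**Figure D4:**
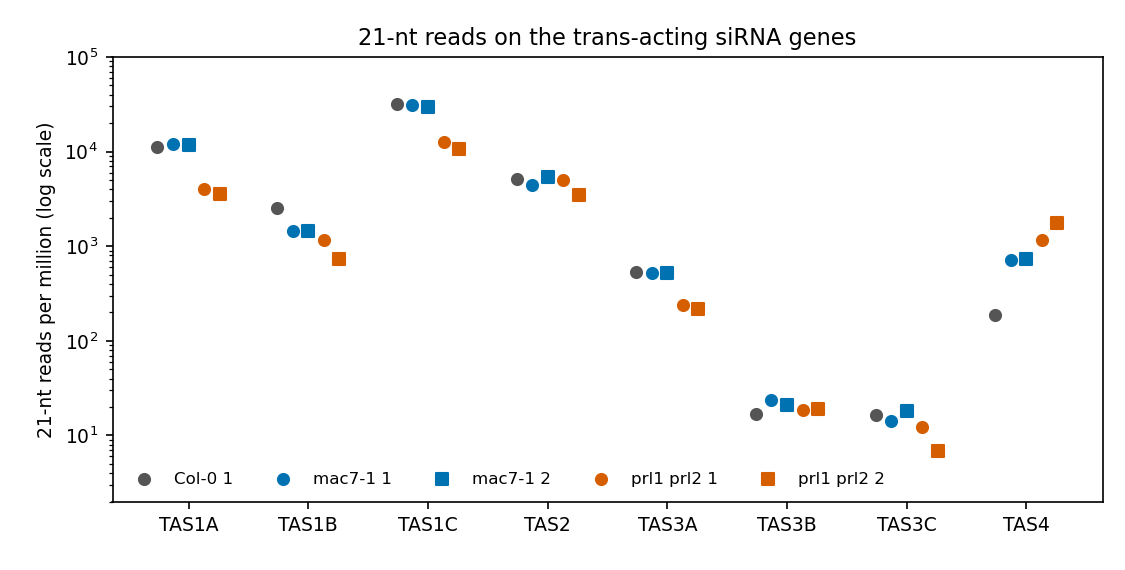
21-nt reads in RPM (log scale) on each TAS gene in each library. In prl1 prl2 the reads of TAS1A, TAS1B and TAS1C lie below Col-0 and those of TAS4 above it.

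24-nt siRNAs were lower at many places in mac7-1. The files held almost only reads that match the reference exactly. Sequence missing from or different in a mutant line would therefore also give 0 reads there, which was not tested for the single windows named here and below. The window on chromosome 1 from 16413001 to 16414000, between genes, went from 16.3 RPM in Col-0 to 0 in mac7-1, at least 26-fold lower (adjusted p = 4.95e-10). A window at BPS3 and the kinase gene MPK4 (chromosome 4, 566001 to 567000) had 113 reads in Col-0 and 1 in mac7-1, a ratio of 196 (95% counting interval 34.5 to 7810; adjusted p = 8.9e-15), and a window at AT2G11910 (chromosome 2, 4805001 to 4806000) went from 4.35 RPM to 0, at least 6.95-fold lower (adjusted p = 0.00132). The largest rises were at AT5G64100 (chromosome 5, 25650001 to 25651000; 0 to 13.8 ± 0.863 RPM, SD, n = 2, at least 12.6-fold, adjusted p = 1.12e-06), AT4G18540 (chromosome 4, 10223001 to 10224000; at least 8.47-fold, adjusted p = 8.18e-05) and the pseudogene AT1G37030 (chromosome 1, 14051001 to 14052000; at least 6.14-fold, adjusted p = 0.000334). edgeR called 731 of 14548 windows, 56 higher and 675 lower, with a median log2 fold change of -0.27. With TMM factors 413 were called, 119 higher and 294 lower, and the median was 0.01; without mac7-1 replicate 1 315 were called. The DESeq2 Wald test called 120, not including those at AT4G18540, AT1G37030 and AT2G11910 (adjusted p = 0.105, 0.153 and 0.0835).

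In prl1 prl2 24-nt siRNAs went both ways, with the same limit on windows with 0 reads in the mutant. Windows that lost them included 1 between genes on chromosome 2 (13702001 to 13703000; 44.9 RPM to 0, at least 145-fold, adjusted p = 4.19e-20), 1 at the pseudogene AT3G21791 (chromosome 3, 7679001 to 7680000; 30.4 to 0, at least 98.2-fold, adjusted p = 6.71e-18) and 1 between genes on chromosome 1 (26185001 to 26186000; 25.003 to 0, at least 80.7-fold, adjusted p = 1.05e-16). Gains were seen at AT3G09960 and AT3G09970 (chromosome 3, 3063001 to 3064000; 0 to 35.8 ± 1.94 RPM, SD, n = 2, at least 32.8-fold, adjusted p = 5.49e-13) and at the long non-coding RNA AT3G05945 (chromosome 3, 11510001 to 11511000; 0 to 22.6 ± 2.91, at least 20.7-fold, adjusted p = 2.41e-10). A window at AT1G29550 (chromosome 1, 10330001 to 10331000) had 1 read in Col-0 and 952 in prl1 prl2, a ratio of 271 (95% counting interval 48.6 to 10700; adjusted p = 1.85e-16). edgeR called 1271 windows, 480 higher and 791 lower, with a median of 0.13; with rRNA reads as the scale it called 823, 59 higher and 764 lower (median -0.23). The DESeq2 Wald test called 348, without the window at 13702001 on chromosome 2 (adjusted p = 0.655).

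**Figure D5:**
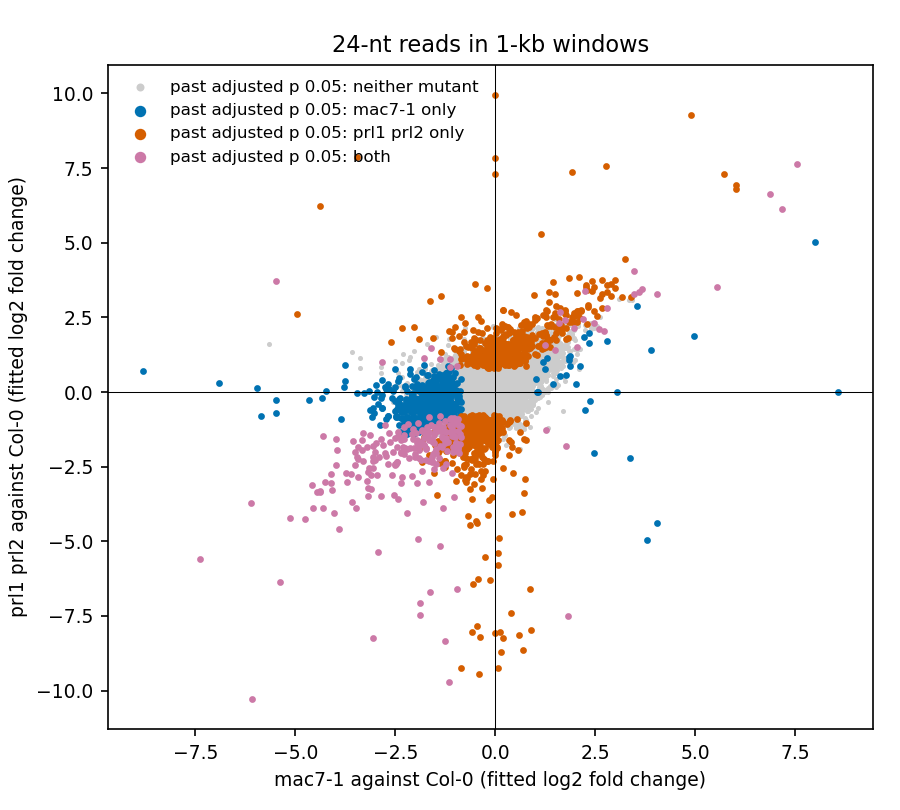
Fitted log2 fold change against Col-0 of 24-nt reads in 14548 windows of 1 kb, in mac7-1 (horizontal axis) and prl1 prl2 (vertical axis), coloured by the mutants in which adjusted p was under 0.05. More of the called windows are lower than higher in either mutant; fitted values of windows with 0 reads in a group have no fixed size.

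Windows with 24-nt siRNAs in mac7-1 and 0 reads in prl1 prl2 lay at the transcription factor genes DOF4.5 (chromosome 4, 11255001 to 11256000; 23.5 ± 5.86 RPM, SD, n = 2, at least 75.7-fold) and DOF4.3 (chromosome 4, 11235001 to 11236000; 23.3 ± 7.14, at least 75.2-fold) and at AT1G19830 (chromosome 1, 6852001 to 6853000; 23.2 ± 0.24, at least 74.8-fold), all with adjusted p = 5.36e-18. With 0 reads in mac7-1, windows higher in prl1 prl2 lay at AT1G29550 (92.1 ± 39.4 RPM, at least 147-fold, adjusted p = 3.25e-23), at AT1G09035 and AT1G06147 (chromosome 1, 9938001 to 9939000; 56.6 ± 5.12, at least 90.4-fold, adjusted p = 3.63e-21) and at AT3G09960 and AT3G09970 (at least 57.1-fold, adjusted p = 5.02e-18). edgeR called 3282 windows between the mutants, 624 higher and 2658 lower in mac7-1. With TMM factors 2299 were called, 1312 higher and 987 lower (median -0.02, against -0.39); without mac7-1 replicate 1 1564 were called and without mac7-1 replicate 2 1833. The DESeq2 Wald test called 832.

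Of the windows called against Col-0, 237 were lower in both mutants, against 36.7 for independent lists and 0 in each of 20 simulations of unchanged mutants. Another 22 were higher in both, against 1.85 for independent lists and 0 in the simulations. The covariance of the fold changes across windows, which are not independent replicates, was 0.36 against 0.185 simulated, and the correlation 0.487 against 0.71. With a single Col-0 library, part of the excess may come from that shared control.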

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

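The tests in this part were chosen after the results were seen, except those of the Col-0 seed stock and of the mature strand, which were written before.

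miRNAs as a set were higher in mac7-1 than in Col-0 relative to all reads, with a median log2 fold change of 0.61. Fewer 24-nt siRNA reads in the mac7-1 libraries are not the whole cause, since the median was still 0.47 with reads of other lengths as the library size. A few abundant miRNAs are not the cause either, as 84.95% of the other tested miRNAs (79 of 93) had positive fold changes. Variation of the single Col-0 library stays open, because the replicates of prl1 prl2 differed by a median of 0.4572. A change in mac7-1 itself and a shift of the Col-0 library cannot be told apart with 1 Col-0 library.

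24-nt siRNAs were lower in both mutants in 237 windows, where a median of 27.8% of the Col-0 level was left in mac7-1 and 27.6% in prl1 prl2. Counting error of the Col-0 reads alone is excluded: with these reads split at random into 2 equal parts, windows lower in both mutants by 1 part had a median of at least 86.96% of that level in the other part, over 10 splits. Sequence missing from the mutant lines stays open for 64 windows without a sequence of 10 or more Col-0 reads. There 29.35% of the Col-0 reads came from sequences read in both mutants. In the other windows 275 of 412 such sequences (66.75%) were above 10% of Col-0 in both mutants. That argues against missing sequence for those 275. It stays open for the rest, among which 48 (11.65% of the 412) were nearly empty in both. Of all windows 14 were left with at most 10% of Col-0 in both. These tests replaced earlier forms, on simulated counts, a Poisson limit and 249 stretches of 25 nt of which 29 were nearly empty, after those forms' results were seen. Variation of the Col-0 library beyond counting error stays open, as do siRNA loci that only the Col-0 seed stock makes, unrelated to the mutations, because that stock is seen in 1 library.

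miR395 was higher in mac7-1. miR395a/d/e was also higher in mac7-1 than in prl1 prl2, by a log2 fold change of 3.655, which argues against low miR395 in the single Col-0 library. It does not exclude that, because prl1 prl2 is itself a mutant and there is no other wild-type library. The library scale is excluded, as the lowest log2 fold change against Col-0 over 6 other scales was 2.78. Reads of the MIR395 genes away from the mature strand argue against retention of that strand alone. They were 8.144-fold and 10.76-fold higher in the mac7-1 libraries (11 reads in Col-0, 79 and 101 in mac7-1). These folds lean on few Col-0 reads, since they were also 2.006 and 3.429 in prl1 prl2 (30 and 81 reads). There miR395a/d/e was at 230 RPM, against 265 in Col-0. Reads away from the strand were at 37.7 ± 7.37 RPM in mac7-1 and 10.8 ± 4.01 in prl1 prl2 (SD, n = 2 each). More MIR395 transcript may therefore be a candidate explanation, as a hypothesis, and neither sulfate supply nor transcription was measured.

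The mutants themselves differed, by the edgeR test between them, in 48 miRNAs. Of the named miRNAs, those higher in mac7-1 than in prl1 prl2 had log2 fold changes of 4.55 (miR395b/c/f), 4.11 (miR157d), 3.82 (miR169f-3p), 3.56 (miR8183), 3.26 (miR158a-5p), 3.04 (miR167c-3p), 2.999 (miR157a/b/c-5p), 2.13 (miR156a/b/c/d/e/f-5p), 2.05 (miR5026), 2.002 (miR393b-3p), 1.98 (miR168b-3p), 1.71 (miR161.1), 1.66 (miR396b-5p), 1.65 (miR159c), 1.59 (miR775), 1.58 (miR5650), 1.29 (miR390a-3p), 1.24 (miR162a/b-3p), 1.18 (miR403-5p) and 0.92 (miR159b-3p). Those lower in mac7-1 had -2.54 (miR398b/c-3p), -2.10 (miR843), -1.47 (miR391-5p) and -1.42 (miR858b). TAS1A and TAS1C differed by 1.65 and 1.39 outside the missing stretch, and by 1.17 and 1.54 over all reads of the intact libraries. These values are those at total reads, where the median over all miRNAs was 0.75; with TMM factors, which are computed from the miRNAs and centre their changes, it was -0.22.

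24-nt siRNAs differed between the mutants in 3282 windows by the same test. Higher in mac7-1 were the windows that begin at 25650001 on chromosome 5 (at least 44.4-fold), 10223001, 11255001 and 11235001 on chromosome 4 (7.56-fold, at least 75.7-fold and at least 75.2-fold), 7679001 on chromosome 3 (at least 43.9-fold), and 26185001 and 6852001 on chromosome 1 (at least 60.7-fold and at least 74.8-fold). Higher in prl1 prl2 were those at 16413001, 10330001 and 9938001 on chromosome 1 (at least 42.3-fold, at least 147-fold and at least 90.4-fold), 4805001 on chromosome 2 (at least 8.41-fold), and 3063001 and 11510001 on chromosome 3 (at least 57.1-fold and 21.5-fold).

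Reads and fragments outside the comparisons were above their level in Col-0 in at least 1 mutant, which was not tested. Reads of 31 to 42 nt were 1.77% in Col-0, 2.92% ± 0.756 (SD, n = 2) in mac7-1 and 4.83% ± 1.17 (SD, n = 2) in prl1 prl2. A chloroplast fragment of 25 nt (104618 to 104642) was at 28847 RPM in Col-0, 53524 ± 1710 in mac7-1 and 49497 in 1 prl1 prl2 library, and 1 of 22 nt (97155 to 97176) at 49534 in Col-0 and 62336 ± 1520 in prl1 prl2, but at 47061 and 38313 in the mac7-1 libraries. The fragment of 31 nt (65654 to 65684) was at 3874, 5748 ± 651 and 7767 ± 2150 RPM in Col-0, mac7-1 and prl1 prl2, and that of 35 nt (46894 to 46928) at 1475, 3240 ± 1170 and 9322 ± 371. The fragment of 26 nt (44675 to 44700) was at 2416 RPM in Col-0 and 5557 ± 1700 in mac7-1, and at 767.5 and 2519 in the prl1 prl2 libraries.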

How the results depend on the processing

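Tests on miRNAs alone outside the missing stretch, with reads of lengths other than 24 nt as library size, on windows with nuclear reads as the scale, and on TAS genes with all reads of the intact libraries were chosen after seeing the data. A mutant left with 1 library was assumed to vary like the other groups, and without a mac7-1 library only the miRNAs seen in all 5 libraries could be fitted. Where a value below differs from that in the report, the cause was not tested, except that filters and leave-outs test fewer features or use fewer libraries.

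For miRNAs in mac7-1 against Col-0, where 11 were called, the counts were 7 with TMM factors, 4 with rRNA reads as the scale, 19 with nuclear reads, 4 at 20 RPM, 34 over MIR genes, 26 with only the groups compared, 6 with reads of other lengths than 24 nt, and 0 to 30 without single libraries. In prl1 prl2, with 18, they were 30 with DESeq2 size factors, 51 over MIR genes, 6 with only the groups compared and 6 to 28 without single libraries. Between the mutants, with 48, they were 30 with rRNA reads, 95 over MIR genes and 13 to 54 without single libraries. miR159b-3p in mac7-1, not called at 0.07, was called lower with TMM factors at -0.60 (adjusted p = 0.0487). The counts over MIR genes are out of 188 genes, not 103 miRNAs. There a read was split evenly over the MIR genes it matched, so genes of 1 family can repeat the same change. The other alternatives, apart from the replicate block given below, stayed within 1.5 times of each count.

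TAS genes called between the mutants numbered 1 with TMM factors and 7 with all reads of the intact libraries, which called 2 in mac7-1; without single libraries the counts were 0 to 2 in mac7-1, 2 to 5 in prl1 prl2 and 2 to 5 between the mutants. Lists called by camera in prl1 prl2 numbered 0 with an estimated correlation and 0 to 2 without single libraries, and 0 to 3 between the mutants. Windows in mac7-1, 731 in the report, numbered 413 with TMM factors, 1149 with rRNA reads, 357 at 30 reads, 120 by DESeq2, 383 with nuclear reads and 315 to 1049 without single libraries. In prl1 prl2, with 1271, they numbered 823 with rRNA reads, 801 at 30 reads and 348 by DESeq2. Between the mutants, with 3282, they numbered 1805 with rRNA reads, 2109 at 30 reads, 832 by DESeq2 and 1564 to 3095 without single libraries. The miRNA share in mac7-1, 3.92 points above Col-0, was 5.28 above with nuclear reads and 5.55 with reads of other ends. Reads of 21 nt in mac7-1 were 2.87 points above and 4.05 with nuclear reads, and reads of 24 nt in prl1 prl2 1.19 and 3.71. The covariance of the mutants' changes was 0.251 with TMM factors, against 0.255.

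The deviations between replicates of the mutants had a correlation of -0.246 over 83 miRNAs. A single difference per mutant cannot exclude a shared batch, and the labels do not say whether an equal replicate number pairs samples. With that number as a block edgeR called 0 miRNAs in mac7-1 (11 at an unadjusted p under 0.05, and 2 by DESeq2), 0 in prl1 prl2 (16, and 6 by DESeq2) and 23 between the mutants, with 2 TAS genes and 2 lists in prl1 prl2.

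Of 32 calls of named miRNAs 7 held under every alternative run and 15 under all but the block and the leave-outs. Of 6 calls of TAS genes 1 and 3 did, and of 18 calls of named windows 14 and 14. No named miRNA call in prl1 prl2 against Col-0 held under every alternative. In mac7-1 against Col-0 only that of miR395b/c/f did, which could not be fitted with the block or without a mac7-1 library. The others that held were between the mutants: miR395b/c/f, miR395a/d/e, miR157d, miR169f-3p, miR8183 and miR398b/c-3p. Calls tested under an alternative kept their direction but fell short of the threshold in 87 of 486 cases for miRNAs, 9 of 54 for TAS genes and 4 of 190 for windows. Named miRNAs that were not called stayed so in 617 of 661 cases, and TAS genes were called in 21. Simulated 2-fold changes were found in 10.2% of cases for windows.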

Other observations

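The gene tests in this part and the test of miR173 were chosen after the results were seen, and the genes are named after their values were seen.

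21-nt reads of protein-coding genes, whose origin was not tested, were lower at several genes in prl1 prl2. At ARF4, a target of TAS3 siRNAs, they fell from 23.9 RPM in Col-0 to 4.18 ± 1.01 (SD, n = 2; log2 fold change -2.47, adjusted p = 0.00099), lower in 2 of 2 libraries, and were at 17.9 ± 1.95 in mac7-1. At AGO2, a target of miR403, they fell from 40.9 to 14.3 ± 3.95 (adjusted p = 0.0389) and at AGO1, a target of miR168, from 12.0 to 5.45 ± 0.169 (adjusted p = 0.0322). At AFB2, a target of miR393, they fell from 53.3 RPM to 25.9 ± 4.14 in mac7-1 (adjusted p = 0.0279) and 26.6 ± 1.48 in prl1 prl2 (adjusted p = 0.0156). The call of AGO1 ended with TMM factors (adjusted p = 0.0573), and those in prl1 prl2 of AGO1, AGO2 and AFB2 ended without mac7-1 replicate 1 (adjusted p = 0.093, 0.0549 and 0.0549) or replicate 2 (adjusted p = 0.0835, 0.0537 and 0.0575), as did that of AFB2 in mac7-1 (adjusted p = 0.22 and 0.146). That of AGO2 also ended without prl1 prl2 replicate 1 (adjusted p = 0.0593).

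A stretch of chromosome 4 with the genes of miR5996 (7882848 to 7882869) and miR3932b-5p (7890695 to 7890715), which were lower in both mutants, had fewer 21-nt reads outside the annotated MIR genes too. MIR5996 lies inside UNE15 and MIR841a inside HTA4, and reads on these MIR genes were left out of the gene counts, but whether the reads counted come from the same precursors was not tested. Those of HTA4 (7884516 to 7885982) fell from 19.2 RPM in Col-0 to 3.12 ± 1.40 (SD, n = 2) in mac7-1 (adjusted p = 0.00443) and 1.78 ± 0.126 in prl1 prl2 (adjusted p = 0.000696). Those of UNE15 (7879558 to 7883926) fell from 34.4 RPM to 9.61 ± 0.813 (adjusted p = 0.0041) and 3.29 ± 0.125 (adjusted p = 0.000115). At AT1G11700 on chromosome 1 reads rose instead, from 2.90 RPM to 18.6 ± 0.134 in mac7-1 (adjusted p = 0.00443) and 26.2 ± 3.94 in prl1 prl2 (adjusted p = 0.000782). In mac7-1 the calls of UNE15 and AT1G11700 ended without replicate 1 (both adjusted p = 0.0569) and those of HTA4, UNE15 and AT1G11700 without replicate 2 (all adjusted p = 0.057).

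The edgeR test called 14 of 213 genes in mac7-1 (7 higher, 7 lower), 42 in prl1 prl2 (7 higher, 35 lower) and 77 between the mutants (57 higher and 20 lower in mac7-1). A read found in several genes was split between them, and genes with over 50% of such reads were 56 of those tested and 4, 17 and 26 of those called, in the same order, so such calls need not be independent of each other. With TMM factors the counts were 16 (7 higher, 9 lower), 47 (14 higher, 33 lower) and 77 (48 higher, 29 lower). In mac7-1 edgeR called 0 genes without mac7-1 replicate 2 (36 at an unadjusted p under 0.05, and 0 by DESeq2).

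TAS1 siRNAs were lower in prl1 prl2 (TAS1A by 3.11-fold outside the missing stretch of sequences and 1.09-fold inside it, in replicate 2), and less of their trigger miR173 was considered as a cause. The trigger strand miR173-5p was not lower: its log2 fold change was 1.18, with 22.8 RPM in Col-0 and 51.8 ± 16.7 in prl1 prl2 (higher in 2 of 2 libraries, adjusted p = 0.113). It was called higher with TMM factors (1.59, adjusted p = 0.0178) and with DESeq2 size factors (1.40, adjusted p = 0.00978). Without prl1 prl2 replicate 1 its log2 fold change was 1.41. Reads of the 3p arm of the same gene were lower, at 3459 RPM in Col-0 and 1773 ± 122 (SD, n = 2) in prl1 prl2. Hardly any reads near miR173-3p began at its annotated 5′ end (0.000% in Col-0, 0.015% and 0.018% in prl1 prl2), so what they are is unclear. The rule set for this test, which asked that the other arm not be lower too, therefore leaves the explanation open, although the trigger strand itself was not lower. No other step of TAS1 siRNA production was measured.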
